A study of Mus musculus with 8 samples.

How the data were processed

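Single-cell gene expression was measured with 10x Genomics 3' libraries, which tag the 3' end of each transcript with a molecular barcode (UMI), in primary cortical neuron cultures from embryonic mouse brains. Per the labels, the cultures were C57BL/6 or Mapt-hTau and were untreated or given brain-derived Tau oligomers named AD, DLB or PSP. This makes 8 groups of 1 library each, with no dose, exposure time or batch given. The titles of 3 libraries carry C57BL/7, C57BL/8 or C57BL/9 where the genotype label gives C57BL/6; the genotype label was used.

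The deposited table holds whole UMI counts per gene and cell for 21158 genes and 73630 cells, with no normalization. Per the submitters' processing notes it was made with Cell Ranger 7.2.0 on mm10. The deposited metadata gives each cell's library, a cluster number, its UMI and gene counts, and the percent of its UMIs from mitochondrial and from ribosomal protein genes. Each cell's UMIs in the table add up to the count in the metadata. How the authors selected cells is not stated. The deposited cells hold at most 15.0 percent mitochondrial UMIs. The lowest UMI count of a cell was 222 in untreated C57BL/6 and 340, 499 and 408 in C57BL/6 AD, DLB and PSP. It was 498 to 501 in the Mapt-hTau libraries, so this lower bound differs with genotype and treatment. The 13 clusters carry no cell type names. Gene positions were taken from the GENCODE annotation of GRCm38 (mm10).

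Clusters were named from marker lists fixed before the data were examined. Each type was scored by the share of its markers raised in a cluster. A raised marker was at least 1.5-fold above the mean of the other clusters, at 10 or more CPM (UMIs scaled to a common total). A cluster took the type with the largest share, given at least 3 raised markers. Where another type came close, the cluster stayed unnamed unless its leading genes favoured the first. Clusters 1, 4 and 6 were called excitatory neuron-like (19137 cells), cluster 2 astrocyte-like (8081 cells) and cluster 3 oligodendrocyte precursor-like (6330 cells). Clusters 1 and 4 each raised 4 of 14 excitatory neuron markers, and cluster 6 raised 7. Clusters 0 and 10 are led by ribosomal RNA (rRNA) related transcripts, and cluster 8 raised markers of both excitatory neurons and astrocytes; these were left unnamed. Classes with at least 50 cells in every library were tested, which left out inhibitory neuron-like cells (49 in the smallest library). Doublets were not removed for the main values: Scrublet's automatic threshold marked 16 of 73630 cells and so did not work here. Leaving out those cells, or the 5 percent of cells with the highest scores, served as alternatives.

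UMIs were summed per library and class, so that the 8 libraries and not the cells are the replicates. The sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05) on R 4.3.3. The additive model of genotype and treatment leaves 3 residual degrees of freedom. It assumes the same oligomer effect in both genotypes, and all its p-values measure only the spread between single libraries left by that model. Genotype may coincide with culture or sequencing run, which the labels do not give. The interaction used exposure as yes or no, with 4 residual degrees of freedom. The 30 functional gene lists and 15 marker lists, fixed before the data were examined, were tested with limma 3.58.1 camera at its preset correlation of 0.01, and again with an estimated correlation. Calls of list members are given over all genes and adjusted over the list alone. DESeq2 1.42.0 and limma-voom were run beside edgeR. Gene length is that of the gene body, introns included. Length quintiles, correlations and median lengths cover genes with an unambiguous position and a mean of 10 CPM or more.

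Genes were named by a rule fixed before the data were examined. Among genes past the test, changed the same way in every pair and at a mean of 10 CPM or more, excluding gene-model names, it takes the 12 largest rises and the 12 largest falls of a contrast. Where fewer than 5 genes pass, it takes the 6 largest rises and falls at 50 CPM or more instead, as an order of size and not as significant. It adds up to 4 passing members of each functional list and Mapt; some genes that the rule names are not reported here. Tables and tests were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and scanpy 1.11.5.

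The libraries hold between 2758792 and 16495028 UMIs, and the excitatory neuron sums between 274055 and 4673476. On simulated changes added to 100 genes each, the genotype test recovered 41 percent of 2-fold and 83 percent of 4-fold changes, the test of any oligomer 28 and 80, AD 18 and 72, DLB 17 and 72, PSP 12 and 64, and the interaction 3 and 19. Unchanged genes called were 17, 10, 14, 17, 5 and 14, in each case more than 5 percent of the calls. Shares of cells carry exact (Clopper-Pearson) binomial intervals and CPM of single libraries exact Poisson intervals, all at 95 percent and for counting error only. With 1 library per group there are no replicates within a group. A fold against libraries with no UMI uses a floor of 3 counts over the group.

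The planned comparison of class shares between genotypes was computed and left out after its values had been seen, because genes that define the clusters differ by genotype. After removal of the 6651 genes that differed by genotype in any tested class, 1 of 14 excitatory, 2 of 14 astrocyte, 1 of 8 precursor and 0 of 8 oligodendrocyte markers remained, and a new clustering gave no cluster that could be called excitatory or precursor-like. The AD, DLB and PSP contrasts share their untreated libraries, so overlaps between them are not given. The 18 planned and 12 added alternatives changed the cell filter, gene filter, scaling, test, clustering, depth and libraries.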

Results

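The data comprise 8 single-cell libraries of primary cortical neuron cultures, 4 from C57BL/6 mice and 4 from Mapt-hTau mice, a line named for human tau. In each genotype, 1 culture was untreated and 3 were given brain-derived Tau oligomers (small soluble assemblies of the microtubule-binding protein tau) named AD, DLB or PSP. The C57BL/6 libraries held 38666 untreated, 11801 AD, 8308 DLB and 6708 PSP cells, with 14293125, 8235769, 16495028 and 6342170 UMIs. The Mapt-hTau libraries held 3023, 3157, 1324 and 643 cells, with 9738626, 11168705, 6196881 and 2758792 UMIs. Median UMIs per cell were 320, 490, 1425.5 and 650.5 in C57BL/6 and 2542, 3075, 4928.5 and 3322 in Mapt-hTau. There were no replicates within a group.

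Although the labels give the cell type as excitatory, the cultures held several classes. Excitatory neuron-like cells made up between 11.0% (95% exact binomial interval 9.32 to 12.8) of the Mapt-hTau DLB library and 51.0% (49.8 to 52.2) of the C57BL/6 PSP library. Astrocyte-like cells made up between 4.94% (4.73 to 5.17) and 27.3% (25.7 to 29.0), both in untreated libraries. Oligodendrocyte precursor-like cells made up between 2.15% (2.00 to 2.30) of the untreated C57BL/6 library and 51.1% (48.3 to 53.8) of the Mapt-hTau DLB library. Transcripts tied to ribosomal RNA (Gm42418, AY036118, Gm15564 and Lars2) took 3.58% of UMIs in untreated C57BL/6 and 0.868% in untreated Mapt-hTau. They took 0.371%, 0.134% and 0.624% in the C57BL/6 AD, DLB and PSP libraries and 0.231%, 0.109% and 0.117% in the Mapt-hTau ones.

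**Figure D1:**
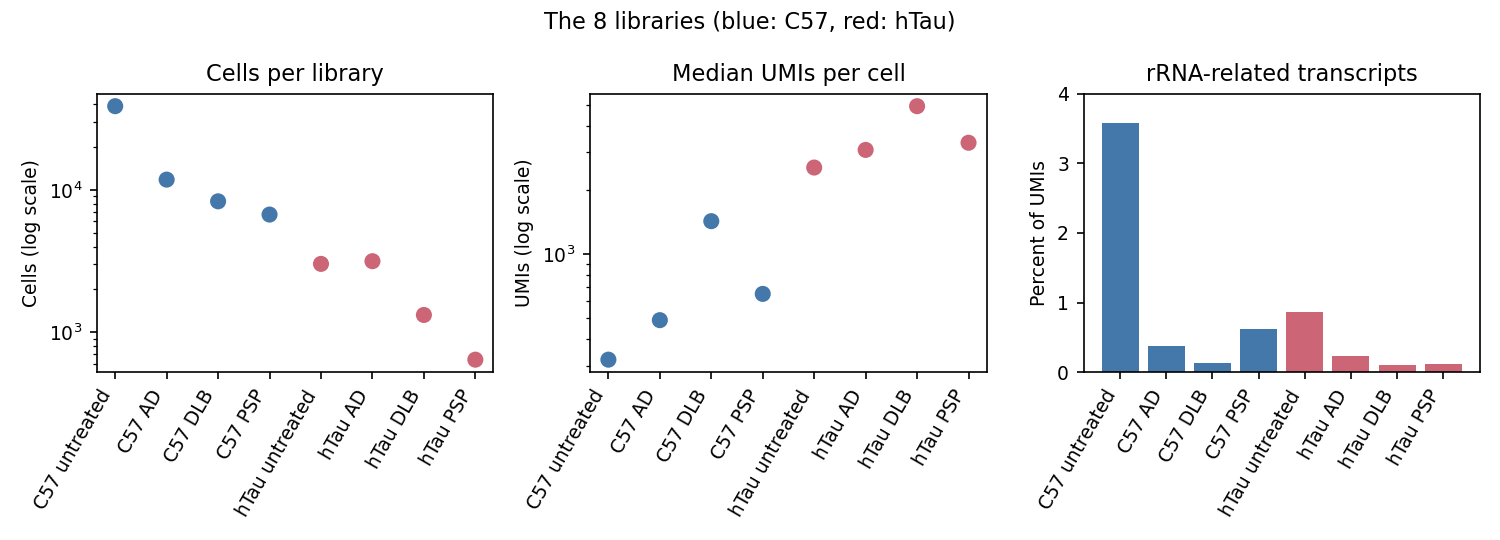
Cells per library, median UMIs per cell (log axis) and percent of UMIs from rRNA-related transcripts in the 8 libraries. The untreated C57BL/6 library had the most cells (38666), the lowest median (320 UMIs) and the highest rRNA-related share (3.58%).

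The tau gene Mapt (chromosome 11, 104231390 to 104332090 on GRCm38, protein-coding) was measured in every library as the gene that the Mapt-hTau line is named for. In excitatory neuron-like cells its CPM in C57BL/6 was 528 untreated (95% exact Poisson interval 503 to 554), 654 with AD (625 to 683), 691 with DLB (667 to 715) and 572 with PSP (542 to 603). In Mapt-hTau it was 414 (370 to 463), 388 (358 to 419), 388 (331 to 453) and 358 (290 to 436). Mapt fell by 0.74 ± 0.20 with genotype (log2 fold change ± SE, edgeR adjusted p = 0.00666, lower in 4 of 4 treatment pairs). The reads are 3' tags counted on the mouse genome and the labels do not say which part of mouse Mapt is altered, so this level checks no label. In cells of at least 1000 UMIs and 500 genes, at most 10 percent mitochondrial, Mapt was at -0.69 (edgeR adjusted p = 0.0611). Over the alternatives with a Mapt value its log2 fold change with genotype ranged from -0.98 to -0.69. Adjusted p ranged from 0.000228 (DESeq2) to 0.0611 (edgeR). Cells of 500 to 1500 UMIs and the removal of the gene length trend are not among these alternatives.

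The genotype comparison asks how neurons that carry the hTau allele differ from C57BL/6 neurons across the 4 treatments. Excitatory neuron-like cells of Mapt-hTau had higher levels of genes induced by neuronal activity and lower levels of many genes for ribosomes, respiration, the proteasome and microtubules. Pcsk1, a prohormone-processing protease (chromosome 13, 75089826 to 75134861), rose by 4.00 ± 0.31 (log2, edgeR adjusted p = 6.20e-08), from a mean of 5.20 CPM in C57BL/6 to 87.4 CPM in Mapt-hTau. Npas4, an activity-dependent transcription factor (chromosome 19, 4984355 to 4990316), rose by 3.39 ± 0.29 (adjusted p = 6.21e-08), and Bdnf, a neurotrophin (chromosome 2, 109674700 to 109727007), by 2.77 ± 0.24 (adjusted p = 6.21e-08). Fosb rose by 3.33, the synaptic pentraxin Nptx2 by 3.09, the secreted neuropeptide precursor Vgf by 3.09 and the nuclear receptor Nr4a1 by 2.93, each higher in 4 of 4 treatment pairs. The ribosomal protein gene Rps23 (chromosome 13, 90922958 to 90924950) fell by 2.42 ± 0.26 (adjusted p = 9.18e-07), and Stmn1, which destabilises microtubules, by 2.10 ± 0.23 (adjusted p = 9.03e-07).

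Among the lists, 14 of 20 measured immediate early genes rose and 6 did not pass (15 rose adjusted over the list alone; median log2 fold change 1.78, camera adjusted p = 1.67e-09). Of 20 presynaptic vesicle genes 11 rose and 9 did not pass (13 adjusted over the list alone; median 0.57, camera adjusted p = 3.38e-05), among them Syp (1.05 ± 0.19) and the priming factor Unc13a (1.04 ± 0.19), which over all cells summed were at -0.13 and -0.18. Of 21 genes of glutamate receptors and the postsynaptic density 9 rose, 1 fell and 11 did not pass (12 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 9.22e-06). Homer1 rose by 1.64 ± 0.19, the kinase Camk2a by 1.59 ± 0.20 and the NMDA receptor subunit Grin1 by 1.57 ± 0.24. With an estimated correlation the adjusted p of each of these 3 lists was 0.281. Of 12 GABA synapse genes 5 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00383), with the receptor subunit Gabrb1 (1.23 ± 0.20) among them. Of 23 calcium handling and channel genes 8 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.00265). Cacna1a rose by 1.24 ± 0.21 and the sodium channel Scn8a by 1.19 ± 0.18. Under an estimated correlation the adjusted p = 0.345 for the GABA list and 0.281 for the calcium list. Of 21 genes for tau uptake and heparan sulfate 6 rose (7, with 1 fall, adjusted over the list alone; camera adjusted p = 0.0147), Chrm3 by 0.94 ± 0.19, and of 21 genes of amyloid precursor processing and Alzheimer risk 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0269). Given an estimated correlation the adjusted p = 0.375 and 0.281 for these lists.

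Of 33 cytosolic ribosomal protein genes 33 fell (33 adjusted over the list alone; median -1.76, camera adjusted p = 7.35e-26), Rps7 by 2.22 ± 0.23. Of 28 nuclear-encoded respiratory chain genes 22 fell (22 adjusted over the list alone; median -1.45, camera adjusted p = 1.63e-11), Cox7c by 1.94 ± 0.26 and Ndufa2 by 1.88 ± 0.24. With an estimated correlation the adjusted p = 0.281 for the ribosomal and 0.375 for the respiratory list. Of 24 proteasome genes 14 fell (18 adjusted over the list alone; camera adjusted p = 8.40e-07), Psma7 by 1.74 ± 0.20. Of 19 oxidative stress genes 10 fell (10 adjusted over the list alone; camera adjusted p = 0.000993), including the antioxidant proteins Txn1 (-2.02 ± 0.23) and Sod1 (-1.59 ± 0.26). Under an estimated correlation the adjusted p = 0.354 and 0.281. Of 26 genes for microtubules and their binding proteins 14 fell and 1 rose (14 and 1 adjusted over the list alone; camera adjusted p = 0.00383), the tubulins Tubb5 by 1.64 ± 0.24 and Tuba1a by 1.40 ± 0.24. Of 13 cytosolic chaperones 5 fell (6 adjusted over the list alone; camera adjusted p = 0.0131), Hspe1 by 1.79 ± 0.22, and of 32 RNA-binding proteins 9 fell (9 adjusted over the list alone; camera adjusted p = 0.00442). Given an estimated correlation the adjusted p = 0.281, 0.281 and 0.426 for these 3 lists.

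In all, 3176 of 12011 tested genes differed by genotype in excitatory neuron-like cells, 1387 higher and 1789 lower in Mapt-hTau. Markers of other cells moved as well: of 10 measured cycling markers 7 fell (10 adjusted over the list alone; median -3.11, camera adjusted p = 2.20e-05, adjusted p = 0.186 with an estimated correlation), Top2a by 5.51 ± 0.48, and the histone gene Hist1h4d fell by 6.55 ± 0.47. The choroid plexus marker Ttr had 362 UMIs in C57BL/6 and 0 in Mapt-hTau neurons, at least 27.6-fold lower. The progenitor marker Fabp7 was at 2059, 1270, 285 and 1130 CPM in C57BL/6 neurons (untreated, AD, DLB and PSP). It was at 172 and 187 CPM in untreated and AD Mapt-hTau neurons. Free RNA from other cells was not tested for the genes that fell with genotype in these neurons. Bcas1, a gene of the oligodendrocyte lineage, rose by 4.31 ± 0.30 and was at a mean of 71.3 CPM in Mapt-hTau neurons against 1900 CPM in precursor-like cells. Median UMIs per neuron ranged from 438 to 1166.5 in C57BL/6 and from 1372 to 2767 in Mapt-hTau. Change went in part with gene length: from the shortest to the longest quintile median log2 fold changes with genotype were -0.60, -0.15, 0.03, 0.12 and 0.29 (Spearman correlation 0.374 across genes, which are not independent replicates). With the trend on gene length removed 2833 genes passed, and the median was -1.15 for ribosomal protein and -0.94 for respiratory chain genes. Over neurons of 500 to 1500 UMIs in every library the count was 434, 111 higher and 323 lower, and over excitatory neuron-like cells that met the stricter cell filter 1741, 699 higher and 1042 lower.

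**Figure D2:**
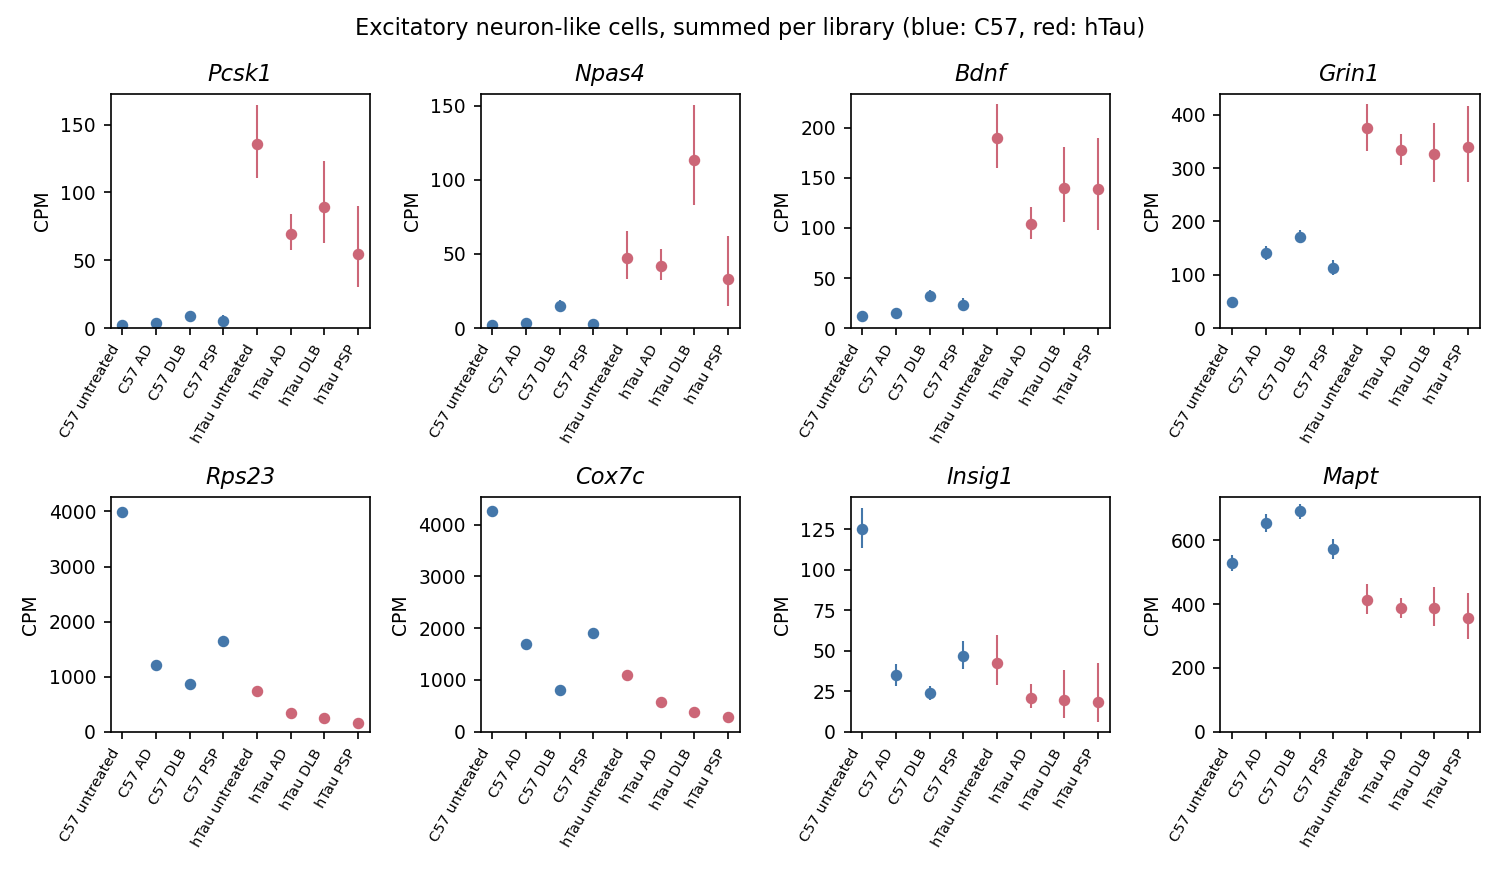
CPM of 8 genes in excitatory neuron-like cells of each library, with exact Poisson 95% intervals as bars. Pcsk1 had between 2.50 and 9.20 CPM in C57BL/6 and between 54.7 and 136 CPM in Mapt-hTau libraries.

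The comparison of any oligomer with no oligomer asks what the exposed cultures share, over 6 exposed and 2 untreated libraries. In excitatory neuron-like cells more genes fell than rose, and those that fell included most of the measured ribosomal protein genes. Kcnc2, a potassium channel of fast-firing neurons (chromosome 10, 112271121 to 112467024), rose by 1.63 ± 0.35 (log2, edgeR adjusted p = 0.00473), from 7.50 to between 18.9 and 27.6 CPM in C57BL/6 and from 7.92 to between 27.0 and 48.2 CPM in Mapt-hTau. The transcription factor Glis3 rose by 1.25 ± 0.25 (adjusted p = 0.00320) and the muscarinic receptor Chrm3 by 1.13 ± 0.23 (adjusted p = 0.00390). Insig1, which restrains cholesterol synthesis and is itself induced when sterols are low (chromosome 5, 28071363 to 28078662), fell by 1.76 ± 0.25 (adjusted p = 0.000194). Its CPM went from 125 to 34.6, 23.5 and 46.7 in C57BL/6 with AD, DLB and PSP, and from 42.2 to 20.7, 19.3 and 18.2 in Mapt-hTau. Nfkb2, a subunit of NF-kB (chromosome 19, 46304320 to 46312385), fell by 2.06 ± 0.30 (adjusted p = 0.000194), and Rps23 by 1.70 ± 0.26 (adjusted p = 0.000393). Each of these genes moved the same way in 2 of 2 genotypes. Nfkb2 is also among the leading genes of the rRNA-led cluster 10, where 566 of 716 cells came from untreated C57BL/6. Its change, here and in the contrasts below, was not separated from that of the rRNA-related transcripts.

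Of 33 ribosomal protein genes 27 fell with any oligomer (32 adjusted over the list alone; median -0.96, camera adjusted p = 1.02e-22), and of 28 respiratory chain genes 15 fell (23 adjusted over the list alone; median -0.90, camera adjusted p = 5.92e-17), Cox7c by 1.59 ± 0.26 and Ndufa1 by 1.44 ± 0.22. Of 24 proteasome genes 7 fell (12 adjusted over the list alone; camera adjusted p = 7.43e-06), Psmb6 by 1.18 ± 0.23, and of 19 oxidative stress genes 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0118), Txn1 by 1.21 ± 0.23. Of 26 axon guidance and adhesion genes 6 rose (13 adjusted over the list alone; median 0.58, camera adjusted p = 1.92e-11), among them Robo2 (0.91 ± 0.26), Unc5c (0.83 ± 0.23) and Slit2 (0.80 ± 0.23). Of 21 glutamate receptor and postsynaptic genes 4 rose (9 adjusted over the list alone; median 0.54, camera adjusted p = 3.28e-07), among them Dlg2 (0.92 ± 0.28), Dlgap1 (0.90 ± 0.26) and Gria1 (0.80 ± 0.25). Of 23 calcium and channel genes 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.000645), with Kcnq3 (1.02 ± 0.24) and Cacna2d1 (0.88 ± 0.25) higher, and of 21 tau uptake genes 1 rose, Chrm3 (3 adjusted over the list alone; camera adjusted p = 0.0375). With an estimated correlation the adjusted p of each of these 8 lists was 0.456. Of 20 cholesterol synthesis genes 3 fell (6 adjusted over the list alone; camera adjusted p = 0.0329; adjusted p = 0.720 with an estimated correlation): Insig1, Mvd (-1.31 ± 0.36) and Fdps (-0.83 ± 0.25). No immediate early gene of 20 passed in edgeR, with 2 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom (camera adjusted p = 0.347). Mapt was at 0.01 ± 0.22 (adjusted p = 0.990).

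**Figure D3:**
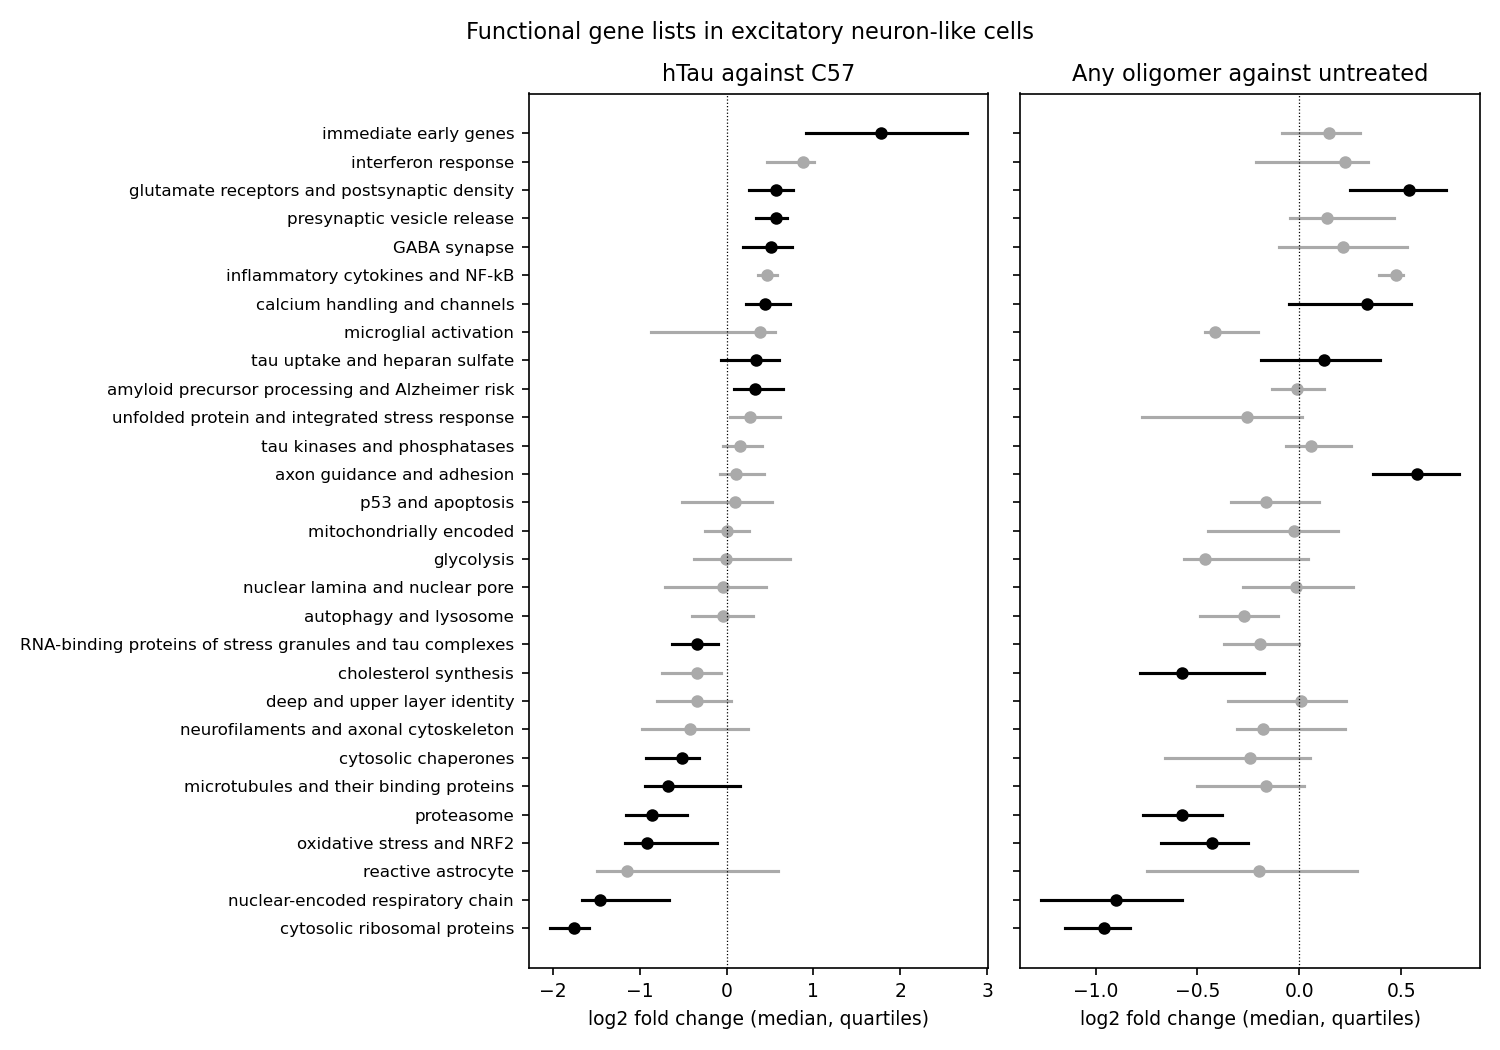
Median log2 fold change and quartiles of gene lists in excitatory neuron-like cells for genotype and for any oligomer, black where the camera adjusted p was under 0.05 and grey otherwise. Ribosomal protein genes had medians of -1.76 with genotype and -0.96 with any oligomer; no list passed with an estimated correlation.

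In all, 1026 of 12011 genes differed with any oligomer, 160 higher and 866 lower. The rRNA-related transcripts fell with them, Lars2 by 3.43 ± 0.27 and AY036118 by 4.06 ± 0.37, and Hist1h4d fell by 5.29 ± 0.28. Hist1h4d is also among the leading genes of the rRNA-led clusters 0 and 10. Change went with gene length: from the shortest to the longest quintile of genes, median log2 fold changes were -0.52, -0.22, -0.04, 0.14 and 0.38, and the correlation across genes, which are not independent replicates, was 0.589 (Spearman). These values cover 9067 genes with a known length and a mean of 10 CPM or more. Among them, genes that rose had a median length of 305566 bases and those that fell 7784 bases. With the trend on gene length removed 351 genes passed. Of the lists, 11 ribosomal protein, 13 respiratory chain and no axon guidance genes then passed in edgeR (medians -0.50, -0.58 and 0.17), and over neurons of 500 to 1500 UMIs none of these 3 lists had a passing gene (medians -0.62, -0.75 and 0.0873). Markers of other cells moved too: of 10 cycling markers 4 fell (5 adjusted over the list alone; median -1.07, camera adjusted p = 0.238), and of 4 microglia markers 2 fell (3 adjusted over the list alone; median -1.34, camera adjusted p = 0.106). Summed CPM of cycling markers was 322 untreated and 211, 93.1 and 221 with AD, DLB and PSP in C57BL/6, and 43.5 and 20.1, 38.6 and 18.2 in Mapt-hTau. Microglia markers were at 112, 119, 48.8 and 111 and at 204, 60.3, 33.8 and 47.4, and inhibitory neuron markers at 182, 210, 318 and 224 and at 174, 215, 191 and 43.8. Without untreated C57BL/6 the count was 401, without C57BL/6 AD 666, without C57BL/6 DLB 451 and without untreated Mapt-hTau 1955. Leaving out untreated C57BL/6 ended the calls of 14 of the 23 genes named here with a call, among them Glis3 (0.97), Insig1 (-0.98), Psmb6 (-0.69) and Fdps (-0.10); leaving out Mapt-hTau PSP ended 8, each of C57BL/6 AD and DLB 7, C57BL/6 PSP 6, untreated Mapt-hTau 4 and Mapt-hTau AD 2, mostly synaptic, guidance and cholesterol genes. Without untreated Mapt-hTau Fdps was at -1.36. Without C57BL/6 DLB Nfkb2 had no UMI left in the DLB group, so its mean over the oligomers gives no fold.

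**Figure D4:**
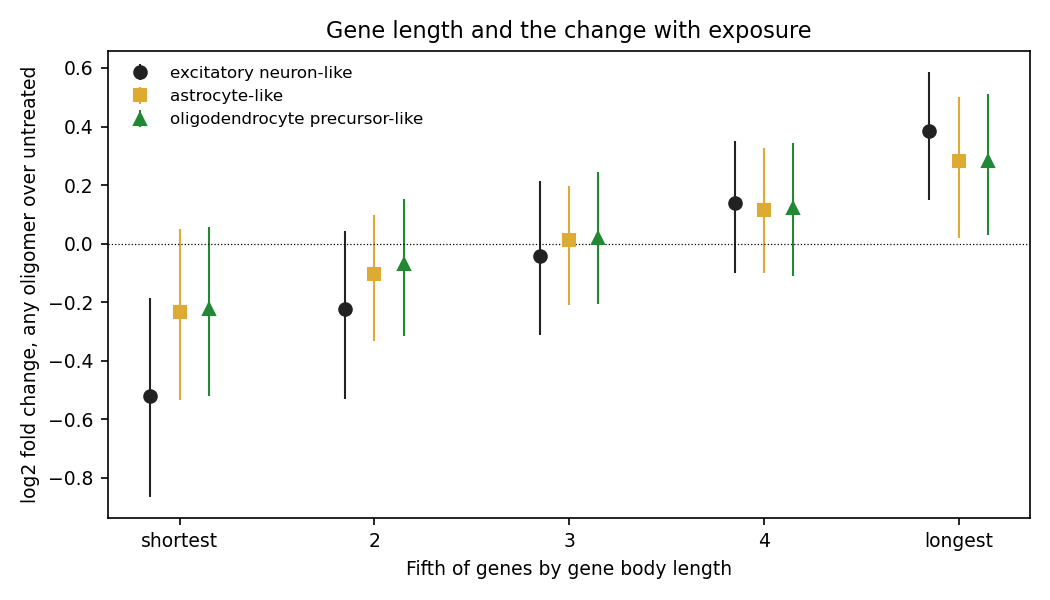
Median log2 fold change with any oligomer by quintile of gene length in excitatory neuron-like, astrocyte-like and precursor-like cells, with quartiles as bars. Medians rose from -0.52 to 0.38 in excitatory neuron-like cells, from -0.23 to 0.28 in astrocyte-like cells and from -0.22 to 0.28 in precursor-like cells.

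With AD oligomers, compared with untreated cultures in 2 libraries each, 81 genes differed in excitatory neuron-like cells in edgeR, 6 higher and 75 lower. The balance differed by tool: 106 higher and 159 lower in DESeq2, with 35 genes shared with edgeR, and 255 and 540 in limma-voom, with 81 shared. The adhesion gene Cntnap5b rose by 1.30 ± 0.26 (log2, edgeR adjusted p = 0.0210), the synapsin gene Syn3 by 1.17 ± 0.27 (adjusted p = 0.0400) and the thyroid hormone receptor Thrb by 1.10 ± 0.25 (adjusted p = 0.0425). Selenoh, a selenoprotein, fell by 1.87 ± 0.35, Lsm6, an RNA-processing factor, by 1.78 ± 0.32, the RNA-binding protein Igf2bp3 by 1.75 ± 0.34, Insig1 by 1.63 ± 0.32 and Psmb6 by 1.24 ± 0.29, each in 2 of 2 genotypes. Hist1h4d fell by 4.86 ± 0.41 and the rRNA-related Lars2 by 3.43 ± 0.38. No ribosomal protein gene of 33 passed over all genes in edgeR, with 30 lower at an unadjusted p under 0.05, 22 in DESeq2 and 21 in limma-voom; 30 fell adjusted over the list alone (median -0.96, camera adjusted p = 1.34e-24). No respiratory chain gene of 28 passed, with 18 lower unadjusted, 6 in DESeq2 and 10 in limma-voom; 16 fell adjusted over the list alone (median -0.78, camera adjusted p = 2.53e-13). No axon guidance gene of 26 passed, with 15 higher unadjusted, 4 in DESeq2 and 6 in limma-voom; 6 rose adjusted over the list alone (median 0.60, camera adjusted p = 4.73e-11). Under an estimated correlation the adjusted p of each of these 3 lists was 0.473. Of 30 lists 13 passed camera, 4 upward and 9 downward, and 0 with an estimated correlation. The count was 135 without untreated C57BL/6, 13 without C57BL/6 AD, 195 without C57BL/6 DLB, 1610 without untreated Mapt-hTau, 193 without Mapt-hTau AD and 437 without Mapt-hTau DLB. Syn3, Thrb, Selenoh, Insig1, Psmb6 and Hist1h4d no longer passed without untreated C57BL/6 (Selenoh at -1.15, Insig1 at -0.92, Psmb6 at -0.79) or without C57BL/6 AD (Selenoh at -1.13, Psmb6 at -0.77), nor Syn3, Thrb and Psmb6 without C57BL/6 PSP, nor Cntnap5b without C57BL/6 AD (1.48) or Mapt-hTau AD (1.20).

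With DLB oligomers 928 genes differed, 149 higher and 779 lower. Of the activity-induced genes, Npas4 rose by 1.81 ± 0.38 (edgeR adjusted p = 0.00382) and Fosb by 1.88 ± 0.45 (adjusted p = 0.0111), in 2 of 2 genotypes. The CPM of Npas4 went from 2.19 to 15.2 in C57BL/6 and from 47.5 to 113 in Mapt-hTau. Kcnc2 rose by 1.96 ± 0.40, Chrm3 by 1.34 ± 0.27 and the semaphorin receptor Nrp1 by 1.31 ± 0.27. Nfkb2 fell by 3.93 ± 0.46 (adjusted p = 2.14e-05), Insig1 by 2.22 ± 0.36, Cox7c by 2.06 ± 0.36 and Rps23 by 2.00 ± 0.37. Of 20 immediate early genes these 2 rose (4 adjusted over the list alone; median 0.64, camera adjusted p = 0.000193), and of 26 axon guidance genes 5 rose (12 adjusted over the list alone; median 0.72, camera adjusted p = 4.05e-10). Of 33 ribosomal protein genes 20 fell (30 adjusted over the list alone; median -1.05, camera adjusted p = 2.01e-18) and of 28 respiratory chain genes 14 (23 adjusted over the list alone; camera adjusted p = 1.71e-15). Given an estimated correlation the adjusted p of each of these 4 lists was 0.523. Of 30 lists 11 passed camera, 6 upward and 5 downward, and 0 with an estimated correlation. Without the C57BL/6 DLB library the count was 16 and the 9 genes named here no longer passed (Fosb at 1.08, Npas4 at 1.41, Insig1 at -1.43; Nfkb2, with no UMI left in the DLB group, gives no fold); without untreated Mapt-hTau the count was 1998. Without untreated C57BL/6 Fosb (1.38) and Insig1 (-1.42) no longer passed, and Fosb was at 2.87 without Mapt-hTau DLB and 2.85 without untreated Mapt-hTau.

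With PSP oligomers 4 genes passed: Gm42418 (-2.33 ± 0.41, edgeR adjusted p = 0.0324), Lars2 (-2.45 ± 0.37, adjusted p = 0.0261), Hist1h4d (-3.84 ± 0.39, adjusted p = 1.32e-05) and Hist1h4h (-2.89 ± 0.50, adjusted p = 0.0261), lower in 2 of 2 genotypes. Gm42418 and Lars2 are rRNA-related and the others are histone genes. All 4 are among the leading genes of the rRNA-led clusters 0 and 10. Gm42418 and Hist1h4h stand outside the naming rule and were chosen after their values were seen. Ordered by size and not significant, Glis3 was at 1.57 ± 0.30 (adjusted p = 0.0549) and Rps23 at -1.68 ± 0.36 (adjusted p = 0.148). No ribosomal protein gene of 33 passed over all genes in edgeR, with 32 lower at an unadjusted p under 0.05, 18 in DESeq2 and 0 in limma-voom; 32 fell adjusted over the list alone (median -0.86, camera adjusted p = 1.37e-19). No respiratory chain gene of 28 passed, with 20 lower unadjusted, 14 in DESeq2 and 0 in limma-voom; 17 fell adjusted over the list alone (median -0.95, camera adjusted p = 2.93e-16). With an estimated correlation the adjusted p of both lists was 0.474. Of 30 lists 11 passed camera, 4 upward and 7 downward, and 0 with an estimated correlation. The 4 calls turned on single libraries: C57BL/6 left out gave 128 untreated, 79 AD, 82 DLB and 11 PSP, and Mapt-hTau left out gave 663 untreated, 55 AD, 169 DLB and 2 PSP. Hist1h4d and Hist1h4h no longer passed without untreated C57BL/6 (Hist1h4h at -1.86) or C57BL/6 PSP, nor Gm42418 (-1.75) and Lars2 (-1.84) without Mapt-hTau PSP; without C57BL/6 PSP Lars2 was at -3.77, and the histone genes, with no UMI left in the PSP group, give no fold.

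The oligomer sources were also compared directly, 2 libraries against 2. Between AD and DLB 55 genes differed, 52 higher with AD and 3 lower. The 3 lower were the immediate early genes Fosb (-2.30 ± 0.45, edgeR adjusted p = 0.0199), Egr4 (-2.21 ± 0.48, adjusted p = 0.0327) and Npas4 (-1.73 ± 0.36, adjusted p = 0.0279); Nfkb2 was higher with AD by 2.61 ± 0.46 (adjusted p = 0.0149), as was the cycling marker Top2a (1.90). Without C57BL/6 DLB 0 genes passed in edgeR (791 were under an unadjusted p of 0.05 with all libraries, and 18 passed in DESeq2 and 279 in limma-voom). The count was 560 without untreated C57BL/6, 15 without C57BL/6 AD, 581 without untreated Mapt-hTau, 325 without Mapt-hTau AD, 168 without Mapt-hTau DLB and 155 without Mapt-hTau PSP, and without C57BL/6 AD none of these 5 genes kept its call (Fosb at -2.20, Nfkb2 at 1.74, Top2a at 1.07; without C57BL/6 DLB Fosb was at -1.52 and Top2a at 3.69), nor Egr4 and Npas4 without Mapt-hTau AD. Between DLB and PSP 92 genes differed, 1 higher and 91 lower with DLB: Npas4 was higher by 2.06 ± 0.43 (adjusted p = 0.0216), and Nfkb2 (-2.99 ± 0.47, adjusted p = 0.00509) and AY036118 (-3.06) were lower. Without C57BL/6 DLB or C57BL/6 PSP 0 genes passed in edgeR (690 under an unadjusted p of 0.05 with all libraries, 16 in DESeq2 and 273 in limma-voom), and Nfkb2, AY036118 and Npas4 lost their calls with each of them (AY036118 at -1.33 without C57BL/6 PSP), AY036118 also without Mapt-hTau DLB and Npas4 without Mapt-hTau PSP. The other libraries gave 355 without untreated C57BL/6, 209 without C57BL/6 AD, 400 without untreated Mapt-hTau, 212 without Mapt-hTau AD, 158 without Mapt-hTau DLB and 182 without Mapt-hTau PSP. Between AD and PSP 0 genes passed in edgeR, with 207 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom; ordered by size and not significant, the cadherin Cdh18 was at 1.00 and Apobec4 at -1.12 (adjusted p = 1 for both). Here 10 genes passed without untreated C57BL/6 or without untreated Mapt-hTau, 1 without C57BL/6 AD and 2 without Mapt-hTau AD or Mapt-hTau PSP.

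The interaction asks whether exposure acted differently in the genotypes. Of 13024 genes 0 passed in edgeR, with 835 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom; without C57BL/6 DLB 83 passed. The test recovered 19% of 4-fold and 3% of 2-fold simulated changes, so most differences of this size would be missed at this depth and design.

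Astrocyte-like cells of Mapt-hTau had higher levels of immediate early genes, of antioxidant genes and of astrocyte and oligodendrocyte markers, and lower levels of neuronal genes. Free RNA from other cells was not tested in this class, so it cannot be told apart for the neuronal and oligodendrocyte genes. Nr4a1 rose by 2.54 ± 0.28 (edgeR adjusted p = 2.63e-07), Egr1 by 1.76 ± 0.20, the detoxifying enzyme Nqo1 by 2.05 ± 0.27 (adjusted p = 3.84e-06), the heme oxygenase Hmox1 by 1.56 ± 0.21 and the glycolytic enzyme Pfkm by 1.76 ± 0.19, in 4 of 4 treatment pairs. Of 18 immediate early genes 12 rose (12, with 2 falls, adjusted over the list alone; median 1.11, camera adjusted p = 0.000214), and of 21 oxidative stress genes 9 rose (9 adjusted over the list alone; median 0.41, camera adjusted p = 0.000401). Under an estimated correlation the adjusted p of both lists was 0.551. Of 20 glycolysis genes 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000912; adjusted p = 0.417 with an estimated correlation). Of 13 reactive astrocyte genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0125; adjusted p = 0.551 with an estimated correlation), among them the adhesion receptor Cd44 (1.01 ± 0.22), Osmr (1.66 ± 0.41) and Stat3 (0.92 ± 0.20). Of 14 astrocyte markers 8 rose (8 adjusted over the list alone; median 0.63, camera adjusted p = 4.55e-06; adjusted p = 0.217 with an estimated correlation), and of 5 oligodendrocyte markers 4 rose (4 adjusted over the list alone; median 4.08, camera adjusted p = 7.97e-07; adjusted p = 0.112 with an estimated correlation), Mbp by 4.08 ± 0.29. Bmp4, also expressed in the oligodendrocyte lineage, rose by 6.20 ± 0.52.

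Of 33 ribosomal protein genes 15 fell in these astrocyte-like cells (24 adjusted over the list alone; median -0.61, camera adjusted p = 8.04e-07) and of 20 presynaptic genes 12 (15 adjusted over the list alone; camera adjusted p = 3.80e-06). Given an estimated correlation the adjusted p of both lists was 0.551. Of 13 excitatory neuron markers 11 fell and 1 rose (11 and 1 adjusted over the list alone; median -1.91, camera adjusted p = 2.29e-07; adjusted p = 0.182 with an estimated correlation), Neurod6 by 3.58 ± 0.32. The neuronal stathmin Stmn2 fell by 3.03 ± 0.26 and Mapt by 1.08 ± 0.20 (adjusted p = 0.000213), and Ttr had 136 UMIs in C57BL/6 and 0 in Mapt-hTau, at least 50.5-fold lower. Excitatory neuron markers summed to 1788, 1462, 1045 and 1476 CPM in C57BL/6 astrocyte-like cells (untreated, AD, DLB and PSP). In Mapt-hTau they summed to 629, 800, 910 and 1067 CPM. In all, 3045 of 11567 genes differed, 1303 higher and 1742 lower. Over cells that met the stricter filter the count was 1642.

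With any oligomer 443 genes differed in astrocyte-like cells, 59 higher and 384 lower. The immediate early gene Ier2 rose by 1.21 ± 0.32 (edgeR adjusted p = 0.0320). Insig1 fell by 1.27 ± 0.27 (adjusted p = 0.00936), Cox7c by 1.28 ± 0.28, Rps23 by 1.26 ± 0.28, the mitochondrially encoded mt-Atp8 by 1.64 ± 0.23 and Lars2 by 2.84 ± 0.27, in 2 of 2 genotypes. Of 28 respiratory chain genes 14 fell (14 adjusted over the list alone; median -0.71, camera adjusted p = 9.19e-10) and of 33 ribosomal protein genes 6 (10 adjusted over the list alone; median -0.56, camera adjusted p = 3.19e-11). Of 13 reactive astrocyte genes 0 passed in edgeR, with 7 higher at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom (median 0.75, camera adjusted p = 1.68e-06). With an estimated correlation the adjusted p of each of these 3 lists was 0.818. Of 10 microglia markers 3 fell (5 adjusted over the list alone; camera adjusted p = 0.00110; adjusted p = 0.574 with an estimated correlation). Of 14 astrocyte markers 1 fell (1 adjusted over the list alone; median 0.33, camera adjusted p = 0.0330; adjusted p = 0.574 with an estimated correlation); their summed CPM went from 5823 to 10481, 8188 and 9200 with AD, DLB and PSP in C57BL/6 and from 11914 to 12819, 10779 and 17273 in Mapt-hTau. Inhibitory neuron markers summed to 224 CPM untreated and 291, 512 and 238 exposed in C57BL/6, and to 294 and 558, 444 and 475 in Mapt-hTau. The count was 119 without untreated C57BL/6, 266 without C57BL/6 DLB, 821 without C57BL/6 PSP, 676 without Mapt-hTau AD, 761 without Mapt-hTau DLB and 286 without Mapt-hTau PSP. Ier2, Insig1 (-0.44), Cox7c (-0.98) and Rps23 (-1.05) no longer passed without untreated C57BL/6, Ier2 (0.95) without untreated Mapt-hTau, Ier2 and Insig1 without Mapt-hTau PSP, Ier2 without Mapt-hTau DLB and Insig1 without C57BL/6 PSP.

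Precursor-like cells of Mapt-hTau had higher levels of myelin genes and lower levels of cell cycle and progenitor genes. Mbp, a structural protein of myelin (chromosome 18, 82475146 to 82585637), rose by 4.62 ± 0.26 (edgeR adjusted p = 2.84e-17), to a mean of 320 CPM in Mapt-hTau, from between 4.63 and 22.1 CPM in C57BL/6. The myelin transcription factor Myrf rose by 4.44 ± 0.35 (adjusted p = 7.00e-14), Enpp6, a phosphodiesterase of newly forming oligodendrocytes, by 6.50 ± 0.34, Bmp4 by 6.10 ± 0.39, Bcas1 by 4.42 ± 0.23 and the kinase Fyn by 2.72 ± 0.21. Egfr, the epidermal growth factor receptor (chromosome 11, 16752203 to 16918158), fell by 4.51 ± 0.23 (adjusted p = 2.84e-16), from a mean of 253 to 11.3 CPM, and the hedgehog effector Gli3 by 4.30 ± 0.39. Each moved the same way in 4 of 4 treatment pairs. Bcas1 and Enpp6 also lead the deposited cluster that defines this class, so the class itself was in part defined by genes that differ between the genotypes.

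Of 5 measured oligodendrocyte markers 5 rose (5 adjusted over the list alone; median 4.62, camera adjusted p = 4.44e-08; adjusted p = 0.0603 with an estimated correlation), among them Cldn11 (5.17 ± 0.31). Of 10 cycling markers 10 fell (10 adjusted over the list alone; median -3.13, camera adjusted p = 1.10e-11; adjusted p = 0.0503 with an estimated correlation), Hist1h1b by 5.97 ± 0.43, and the mitotic kinesin Kif11 fell by 4.45 ± 0.36. Of 10 progenitor markers 8 fell and 1 rose (8 and 1 adjusted over the list alone; median -1.82, camera adjusted p = 8.27e-05; adjusted p = 0.106 with an estimated correlation). Of 20 cholesterol synthesis genes 15 rose (16 adjusted over the list alone; median 0.66, camera adjusted p = 0.000751; adjusted p = 0.849 with an estimated correlation), Lss by 1.51 ± 0.31. Of 26 axon guidance genes 15 fell and 5 rose (16 and 5 adjusted over the list alone; median -1.35, camera adjusted p = 0.000751), and of 17 cortical layer genes 12 fell and 2 rose (12 and 2 adjusted over the list alone; median -1.51, camera adjusted p = 0.000145). Under an estimated correlation the adjusted p of both lists was 0.316. Of 26 microtubule genes 13 fell and 4 rose (13 and 4 adjusted over the list alone; camera adjusted p = 0.00342; adjusted p = 0.849 with an estimated correlation), Stmn1 by 2.77 ± 0.23. Of 13 excitatory neuron markers 12 fell and 1 rose (12 and 1 adjusted over the list alone; median -1.93, camera adjusted p = 1.19e-08; adjusted p = 0.139 with an estimated correlation). Free RNA from neurons was not tested for these markers or for Mapt. Mapt fell by 0.57 ± 0.18 (adjusted p = 0.0104) and no longer passed without C57BL/6 AD, Mapt-hTau AD or untreated Mapt-hTau, at -0.48, -0.48 and -0.51. In all, 3742 of 11262 genes differed, 1648 higher and 2094 lower.

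**Figure D5:**
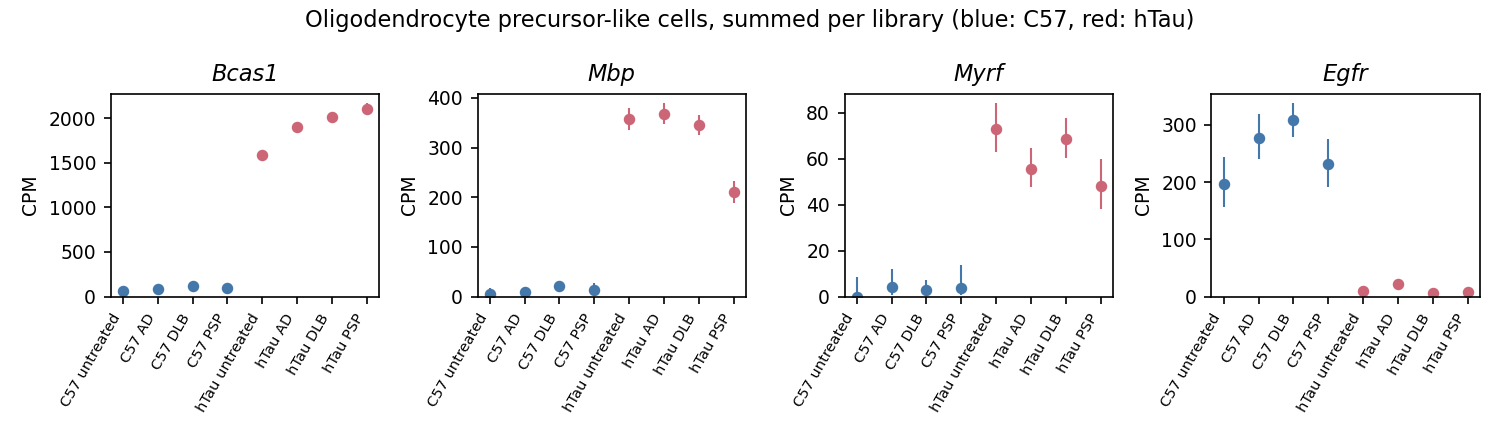
CPM of Bcas1, Mbp, Myrf and Egfr in precursor-like cells of each library, with exact Poisson 95% intervals as bars. Mbp had between 4.63 and 22.1 CPM in C57BL/6 and between 210 and 368 CPM in Mapt-hTau libraries; Egfr had between 197 and 307 CPM and between 6.90 and 21.0 CPM.

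With any oligomer 665 genes differed in precursor-like cells, 156 higher and 509 lower. Nes, the intermediate filament of progenitors, rose by 2.18 ± 0.46 (edgeR adjusted p = 0.00189), the glial transcription factor Sox9 by 1.33 ± 0.24 (adjusted p = 0.000331) and the reactive astrocyte gene Serpina3n by 2.95 ± 0.73 (adjusted p = 0.00867), in 2 of 2 genotypes. Ndufa1 fell by 1.21 ± 0.21, Cox7c by 1.19 ± 0.24, Rps23 by 1.16 ± 0.24 and Lars2 by 3.38 ± 0.53. Of 28 respiratory chain genes 14 fell (14 adjusted over the list alone; median -0.56, camera adjusted p = 1.31e-09; adjusted p = 0.841 with an estimated correlation) and of 33 ribosomal protein genes 8 fell (10 adjusted over the list alone; median -0.46, camera adjusted p = 5.82e-08; adjusted p = 0.859 with an estimated correlation). Markers of other cells also moved. Of 11 inhibitory neuron markers 2 rose (2 adjusted over the list alone; median 0.55, camera adjusted p = 0.235), their summed CPM going from 777 to between 1389 and 2203 in C57BL/6 and from 1111 to between 1870 and 2308 in Mapt-hTau. Of 13 excitatory neuron markers 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0117) and of 3 microglia markers 1 fell (2 adjusted over the list alone; camera adjusted p = 0.0271), with adjusted p = 0.458 for both with an estimated correlation. Microglia markers summed to 130 CPM in untreated Mapt-hTau and to 48.6, 21.8 and 15.6 with AD, DLB and PSP, and to 85.6, 99.7, 27.8 and 106 in C57BL/6 untreated, AD, DLB and PSP. Of 8 oligodendrocyte precursor markers, which name the class, 1 rose (3 adjusted over the list alone; median 0.32, camera adjusted p = 0.0454; adjusted p = 0.458 with an estimated correlation), and their summed CPM went from 1210 to 2645, 2311 and 2132 with AD, DLB and PSP in C57BL/6 and from 2849 to 3935, 4614 and 5186 in Mapt-hTau. Of 10 progenitor markers 3 rose (3, with 1 fall, adjusted over the list alone; camera adjusted p = 0.0616). The count was 298 without untreated C57BL/6, 319 without untreated Mapt-hTau, 1054 without Mapt-hTau DLB and 257 without Mapt-hTau PSP. Nes (1.86), Cox7c (-0.99), Rps23 (-1.06) and Lars2 (-3.57) no longer passed without untreated C57BL/6, Serpina3n without Mapt-hTau DLB, Mapt-hTau PSP or untreated Mapt-hTau, and Lars2 without untreated Mapt-hTau.

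Class shares were compared between 6 exposed and 2 untreated libraries in a two-sided exact permutation test over 28 assignments, in which the smallest attainable p is 1 of 28. The test ignores genotype, and a single class could not pass it once adjusted, so it does not show that shares were alike. In C57BL/6, excitatory neuron-like cells made up 17.6% of untreated and 37.7% to 51.0% of exposed libraries, and precursor-like cells 2.15% and 8.41% to 9.21%. In Mapt-hTau they made up 14.0% of the untreated and 11.0% to 20.8% of exposed libraries, and 37.7% and 33.0% to 51.1%. The lowest p was 0.0714 (adjusted p = 0.571), for fibroblast or meningeal-like cells, 0.520 percentage points higher in exposed libraries. Excitatory neuron-like cells averaged 15.8% in untreated and 28.7% in exposed libraries (exact permutation p = 0.321, adjusted p = 0.643), a difference that turned to -1.11 points over cells of at least 500 UMIs and to -3.62 without clusters 0 and 10, and was 3.47 under the stricter cell filter and 14.6 with the own clustering. The fibroblast difference turned to -0.400 over cells of at least 500 UMIs. The rRNA-led cluster 0 held 68.1% of untreated C57BL/6 cells and at most 25.6% of any other library, which lowers the other shares there. Precursor-like cells were 5.91 points higher (exact permutation p = 0.607, adjusted p = 0.694).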

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

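The tests on axon guidance genes, on free RNA, on precursor-like cells as a comparison for immediate early genes, and on other splits of the libraries were chosen only after the result was seen.

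Among the 4 C57BL/6 libraries the untreated one lay far from the others in 3 measures. It held 38666 cells against 6708 to 11801, rRNA-related transcripts took 3.58% of its UMIs against 0.134% to 0.624%, and 2.15% of its cells were precursor-like against 8.41% to 9.21%. Cluster 0 held 68.1% of its cells and so lowers that share; the C57BL/6 libraries ranged from 6.96% to 9.59% over cells of at least 500 UMIs and from 7.06% to 12.5% without clusters 0 and 10. Among the 4 Mapt-hTau libraries rRNA-related transcripts took 0.868% of UMIs in the untreated one against 0.109% to 0.231%. These 4 came from 34 groups of 4 libraries, of which chance marks about 1 in 20. A signal also appeared in cells outside the tested classes: cluster 8 held 6.93% of cells on average in the 4 Mapt-hTau libraries (SD 2.04, range 5.13 to 9.00) and 1.97% in the 4 C57BL/6 libraries (SD 1.49, range 0.453 to 3.62). Genes that lead this cluster, among them Nptx2, Bdnf and Pcsk1, were themselves higher in Mapt-hTau neurons, and cluster 0 lowers the C57BL/6 shares, so this is no test of a difference in cell types.

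In excitatory neuron-like cells exposed to any oligomer, 27 of 33 ribosomal protein genes fell (median log2 fold change -0.96, quartiles -1.15 to -0.83). Of 26 axon guidance genes 6 rose (median 0.58, quartiles 0.36 to 0.78). Neither list passed camera with an estimated correlation. Over neurons of 500 to 1500 UMIs the ribosomal median was -0.62 (quartiles -0.79 to -0.44), past the bound set beforehand for excluding depth per cell. There 27 calls became 0 in edgeR, with smaller folds and with 19 and 31 cells left in Mapt-hTau PSP and DLB. Depth still differed inside this window. In C57BL/6, 2149 untreated neurons held 1411733 UMIs and 2088 DLB neurons 2010155. In Mapt-hTau, 241 untreated neurons held 243570 UMIs and 31 DLB neurons 28457. The bound alone therefore does not exclude depth. The axon guidance median was 0.0873 in that window and 0.17 with the trend on gene length removed, and none of its 6 calls was kept in either, so depth or gene length may account for that part. With the length trend removed the ribosomal median was -0.50 (quartiles -0.77 to -0.34, 11 of 33 genes past the test), just short of the bound set beforehand for excluding gene length, and 0 of 423 untreated Mapt-hTau neurons had under 0.1 percent rRNA-related UMIs, so gene length and cells rich in rRNA-related transcripts cannot be told apart from exposure here. The CPM of the nuclear RNA Malat1 in these neurons was 12916 in untreated C57BL/6 and 29815, 32598 and 17391 with AD, DLB and PSP. In Mapt-hTau it was 26277 untreated and 34850, 41011 and 63173 exposed, above C57BL/6 in each treatment. Whether the lists moved with the share of nuclear RNA was not tested. A response to the oligomers stays open. The additive model tests exposure, but against 1 untreated library per genotype, so it cannot be told apart from other traits of those libraries.

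Immediate early genes were higher in Mapt-hTau neurons (median 1.78, quartiles 0.91 to 2.77). In cluster 1 alone the median was 1.91 (quartiles 0.77 to 2.48), which argues against a shift between clusters of the excitatory class. With the level in Mapt-hTau precursor-like cells subtracted from Mapt-hTau neurons alone, the median was 1.11 (quartiles -0.32 to 2.10, 13 of 20 genes above 0), so free RNA from other cells cannot be told apart for part of the list; subtraction in both genotypes gave 2.85 but rests on the floor of 1 CPM. A response shared by every cell class cannot be told apart either, since the median in precursor-like cells was 0.33 with a spread across 0 (quartiles -0.58 to 0.77). In astrocyte-like cells the list was higher too (median 1.11, quartiles 0.21 to 1.51, 12 of 18 genes past the test). A difference in neuronal activity with genotype may be a candidate explanation, but culture, run and the handling of the cells may coincide with genotype and were not tested. Neurons also held more UMIs per cell in Mapt-hTau, and the list was not tested over cells of matched depth. Over neurons of 500 to 1500 UMIs the genotype calls among all genes went from 3176 to 434, 111 of them higher.

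Oligodendrocyte markers were higher in Mapt-hTau precursor-like cells (median 4.62, 5 of 5 markers past the test). With the level in Mapt-hTau neurons subtracted from these cells alone the median was 4.71 (quartiles 3.17 to 5.25), which argues against free RNA from other cells, and subtraction in both genotypes gave 5.38. Over precursor-like cells of 500 to 1500 UMIs it was 4.25 (quartiles 3.08 to 4.99, 4 measured markers), which argues against depth per cell. A further differentiation of this lineage with genotype may be a candidate explanation, while culture age and sequencing run, which the labels do not give, and the cluster definition stay open.

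Of the 35 splits of the 8 libraries into 4 and 4, 32 could be fitted. In each tested class 1 of the 32, the split by genotype, gave as many changed genes: 3176 in excitatory neuron-like cells with a highest other of 0, 3045 in astrocyte-like cells with a highest other of 1, and 3742 in precursor-like cells with a highest other of 0. The other splits mix the genotypes, so that the genotype difference enters their residual spread, and many follow treatment in part. Only 8 of the splits part the libraries of each treatment as genotype does, with a highest other of 0 in edgeR in each class, which are too few for a share under 0.05. A culture or run that coincides with genotype would give the same split.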

How the results depend on the processing

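The alternatives with the highest 5 percent of Scrublet scores left out, at least 500 or 500 to 1500 UMIs, without rRNA-related transcripts, without untreated C57BL/6 and Mapt-hTau PSP together, cluster 1 alone, cluster 8 added, own clustering for gene counts, gene length, shares without clusters 0 and 10 or under the stricter filter, and all in astrocyte-like and precursor-like cells were chosen after seeing the data.

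Within 1.5 times of their count were, in excitatory neuron-like cells, genotype in 17 of 20 alternatives, any oligomer in 11 of 20, AD in 7 of 17, DLB in 10 of 17, PSP in 6 of 17, AD against DLB in 7 of 17, AD against PSP in 13 of 17, DLB against PSP in 8 of 17 and the interaction in 13 of 16. In the other classes genotype was in 24 of 31 and any oligomer in 22 of 30. These do not count leaving out 1 library, which moved by over 1.5 times genotype in 0 of 8, any oligomer in 4, AD in 6, DLB in 2, PSP in 8, AD against DLB in 7, AD against PSP in 5, DLB against PSP in 8 and the interaction in 1 of 6, and in astrocyte-like and precursor-like cells genotype in 0 and 0 and any oligomer in 6 and 4. For the values below the cause was not tested.

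With the stricter cell filter the counts in excitatory neuron-like cells were 1741 for genotype, 310 for any oligomer, 33 for AD, 307 for DLB, 2 for PSP, 1 for AD against PSP and 0 for DLB against PSP, and genotype and any oligomer gave 1642 and 243 in astrocyte-like and 2278 and 274 in precursor-like cells. Thinned to the shallowest library they were 1693 for genotype, 571 for any oligomer, 396 for DLB, 30 for PSP, 0 for AD against DLB, 0 for DLB against PSP and 1 for the interaction, with genotype at 1359 in astrocyte-like and 2097 in precursor-like cells. Over cells of 500 to 1500 UMIs genotype gave 434 and any oligomer 106, and genotype 1746 in precursor-like cells. With all cells summed any oligomer gave 55, DLB 134, and AD, PSP, AD against DLB and DLB against PSP 0 each in edgeR. Without untreated C57BL/6 and Mapt-hTau PSP any oligomer gave 247 (160 in astrocyte-like and 131 in precursor-like cells), DLB 601, PSP 19, AD against DLB 608, AD against PSP 12 and DLB against PSP 392.

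In cluster 1 alone any oligomer gave 451, AD 17, DLB 493, PSP 1, AD against DLB 1 and DLB against PSP 4. With cluster 8 any oligomer gave 1668, AD 658 and AD against DLB 178. In an own clustering any oligomer gave 596, AD 19, PSP 2, AD against DLB 7, AD against PSP 1, DLB against PSP 45, and genotype 1915 in precursor-like cells. With the gene length trend removed any oligomer gave 351. With the DESeq2 Wald test AD gave 265, DLB 613, PSP 209, AD against DLB 18, DLB against PSP 16, the interaction 2, and any oligomer 415 in precursor-like cells. With limma-voom AD gave 795, DLB 1548, AD against DLB 279 and DLB against PSP 273. With no filter beyond 1 UMI AD gave 326, PSP 110, AD against DLB 319, AD against PSP 1, DLB against PSP 224 and the interaction 67. At a mean CPM of at least 10 AD gave 49, PSP 2, and any oligomer 265 in astrocyte-like cells. Without the highest 5 percent of Scrublet scores AD gave 149 and AD against DLB 98. PSP gave 2 over cells of at least 500 UMIs and 2 without rRNA-related transcripts. Genotype gave 1849 in astrocyte-like cells with no treatment term. With exposure as 2 levels any oligomer gave 126 in astrocyte-like and 317 in precursor-like cells.

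Leaving out each library in turn, where a group without its library is assumed to vary like the others, gave 2366 to 3080 for genotype, 401 to 1955 for any oligomer, 13 to 1610 for AD, 16 to 1998 for DLB, 2 to 663 for PSP, 0 to 581 for AD against DLB, 0 to 10 for AD against PSP, 0 to 400 for DLB against PSP and 0 to 83 for the interaction. The interaction could be fitted without 6 of the libraries and not without an untreated one. In astrocyte-like cells genotype gave 2183 to 2861 and any oligomer 119 to 821, and in precursor-like cells 2940 to 3571 and 257 to 1054.

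Camera with an estimated correlation called 0 functional lists in each of the 9 contrasts tested. The fry test called 14 for genotype in excitatory neuron-like cells (14 in camera at its preset correlation), 4 in astrocyte-like cells (13) and 3 in precursor-like cells (4), and 0 for any oligomer, AD, DLB and PSP in excitatory neuron-like cells and for any oligomer in astrocyte-like and precursor-like cells.

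Shares of classes, exposed minus untreated, kept their direction in 31 of 42 alternatives. Astrocyte-like cells (0.925 points) were at -3.60 in an own clustering, -6.24 over cells of at least 500 UMIs, -3.14 without clusters 0 and 10 and -6.71 with the stricter filter. Fibroblast or meningeal-like cells (0.520) were at -4.46, -0.400 and -0.894 in the own clustering, over 500 UMIs and with the stricter filter; the class so named in the own clustering averaged 10.7% of C57BL/6 cells against 0.998% as deposited and is not the same class. Cycling-like cells (1.98) were at -0.155 over 500 UMIs and -4.45 with the stricter filter. Excitatory neuron-like cells, higher in exposed libraries before, were at -1.11 over cells of at least 500 UMIs and -3.62 without clusters 0 and 10. Mapt CPM over all cells was 614, 497 and 455 in C57BL/6 AD, DLB and PSP and 245, 291 and 297 in Mapt-hTau untreated, AD and DLB.

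Of the genes named with a call, 13 of 31 for genotype, 1 of 23 for any oligomer and 0 for AD, DLB, PSP, AD against DLB and DLB against PSP passed in every one of up to 26 alternatives in excitatory neuron-like cells. In astrocyte-like cells these were 9 of 13 for genotype and 0 of 6 for any oligomer, and in precursor-like cells 13 of 15 and 1 of 7. For any oligomer in excitatory neuron-like cells the gene was the rRNA-related Lars2, which had a value in 25 alternatives. In precursor-like cells it was Sox9. The up to 26 alternatives in excitatory neuron-like cells leave out cells of 500 to 1500 UMIs and the removal of the gene length trend. With all cells summed Syp was at -0.13 and Unc13a at -0.18 with genotype, Mapt at -0.16 with any oligomer and Top2a at -0.34 for AD against DLB. Without untreated C57BL/6 and Mapt-hTau PSP, Fdps was at 0.0351 and Mapt at -0.0754 with any oligomer. Mapt with any oligomer was at -0.0025 with the DESeq2 Wald test, -0.0023 with DESeq2 size factors, -0.0164 at a mean CPM of at least 10, -0.22 when thinned and -0.0104 without mitochondrial and ribosomal protein genes. Leaving out 1 library gave -0.0468 to 0.0655 for Mapt. In simulations at this depth and with 1 library per group, the PSP contrast recovered 12 percent and the interaction 3 percent of 2-fold changes.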

Other observations

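No test was added for this part, and its values were picked after the results were seen.

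Cluster 8, which is in none of the tested classes, held 1419 cells with a median of 2951 UMIs. Its mean CPM over the 4 libraries of a genotype was, in C57BL/6 and Mapt-hTau, 17.1 and 267 for Pcsk1, 30.3 and 218 for Npas4, 32.7 and 429 for Nptx2, 88.1 and 456 for Bdnf, and 68.9 and 269 for Vgf.

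Several lists did not pass camera for genotype in excitatory neuron-like cells. Of 21 genes of the unfolded protein and integrated stress response 4 rose and 2 fell (camera adjusted p = 0.0698), of 20 autophagy and lysosome genes 2 and 4 (0.705), of 31 tau kinases and phosphatases 6 and 1 (0.0726), and of 12 neurofilament and axonal cytoskeleton genes 1 and 6 (0.226). Of 3 measured interferon response genes 0 passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 in DESeq2 or limma-voom.

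In astrocyte-like cells with genotype, of 22 calcium handling and channel genes 12 fell (median -0.74, camera adjusted p = 0.000912), of 20 cholesterol synthesis genes 8 fell (median -0.46, camera adjusted p = 0.00506), and of 10 cycling markers 9 fell (median -1.79, camera adjusted p = 7.97e-07). With an estimated correlation the adjusted p = 0.551, 0.551 and 0.175.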
